A study of Mus musculus with 3 samples.

How the data were processed

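The series held 3 droplet single-cell RNA libraries of mouse intestinal epithelium, 1 from wild-type (WT) ileum, 1 from WT colon and 1 from the colon of mice lacking Satb2 (KO colon). Per the labels' protocols, live Epcam-positive, CD45-negative and CD31-negative cells of adult mice were sorted and processed with the 10x Genomics droplet workflow. Floxed Satb2 was combined with a Villin-driven, tamoxifen-inducible Cre recombinase in the KO, and floxed mice without Cre served as controls. Each group held 1 library, and the number of mice behind each library was not given in the sources used here.

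The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. Per the file headers, both WT matrices were written by version 3.0.2 of the counting software and the KO matrix by version 3.1.0. The submitters' processing notes name the mouse genome mm10 and Seurat, with no version and no role. The gene names of the KO matrix carry hg19 and mm10 prefixes, so that library was counted against a joint human and mouse reference, while the WT files hold mouse genes only. A read that fits both genomes of a joint reference can be discarded, which would lower mouse counts in the KO file alone. The aligner is not given in the sources used here. The same 31053 mouse genes, matched by Ensembl identifier, were used from every file, and hg19 genes served only to filter barcodes.

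Cells were kept with at least 500 detected mouse genes, at least 1000 mouse UMIs, under 25% of UMIs from mitochondrial genes and under 5% of UMIs from hg19 genes. Doublets called by Scrublet within scanpy 1.11.5 were removed. Scrublet called 1 WT ileum, 1 WT colon and 2 KO cells, under 0.5% of each library, so it was taken not to have worked and doublets were treated as still present. Kept cells numbered 4286, 3970 and 4736 in WT ileum, WT colon and KO colon. The filter on mitochondrial UMIs removed 1266, 1553 and 756 barcodes in that order.

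Each library was clustered on its own, so that a difference between libraries could not make a cluster. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components, and a graph of 15 neighbours was split by the Leiden method at resolution 1. Clusters were named from 9 marker lists fixed before the data were examined, while the scoring rule was set after seeing the data. For each class, the mean log2 level of its markers (counts per 1000000 UMIs, CPM, plus 10) was placed between the 10th percentile of the library's clusters, set to 0, and the highest cluster of any library, set to 1. A cluster took the class in which it stood highest, at 0.3 or above, with at least 3 markers detected in 10% of its cells at 2-fold over the lower quartile of clusters. A class was passed over where the 10 leading genes of the cluster (detected in 25% of its cells) held more markers of another class, and a lower-placed class then needed 2 markers among them. A cluster with a low median UMI count and no marker among its leading genes was left unnamed. Stem-like and cycling-like clusters were read together. Unnamed clusters held 1.80% (1.42 to 2.24) of WT ileum cells, 7.003% (6.23 to 7.84) of WT colon cells and 0 of 4736 KO cells. The unnamed WT colon cluster was led by Hao2, Gsdmc2 and Hmgcs2, and the unnamed WT ileum cluster by Ms4a18, Apol10a and Ces1f.

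With 1 library per group there was no replicate, and no test, standard error or p-value across conditions was computed. UMIs were summed over the cells of a class and given as CPM with exact Poisson intervals. Ratios of sums carry exact conditional binomial intervals and shares of cells or UMIs exact Clopper-Pearson intervals. All intervals are at 95% and cover counting error only, not differences between mice, sorts or libraries. A count under 3 was set to 3 in ratios, and a ratio against 0 counts is given as a lower bound. Cells are not replicates, and every difference compares these libraries, not the conditions.

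The 23 gene lists fixed before the data were examined were small-intestinal (SI) bile acid handling, SI lipid absorption, SI brush border enzymes, SI nutrient transporters, colonic ion and water transport, colonic epithelium other, Paneth, stem cell, proliferation, goblet secretion, enteroendocrine hormones, patterning transcription factors, antimicrobial lectins, MHC class II, interferon response, xenobiotic metabolism, cholesterol synthesis and dissociation stress, and 5 lists of cells that the sort should exclude (T lymphocyte, B and plasma cell, myeloid, stroma and endothelium, erythrocyte). A list was described by its median log2 ratio over members with at least 20 UMIs in both libraries together, with an interval from 500 Poisson draws. The percentile of that median was taken among 10000 random lists of the same size matched on mean expression. Members at least 2-fold higher, at least 2-fold lower and between were counted. The ileal share was the UMIs of the 4 SI lists divided by those of the 4 SI and 2 colonic lists, also per cell after thinning each cell to 2000 UMIs. Some list members are also markers of the absorptive class, and medians without them are given. Ang4 and Retnlb of the colonic lists are also goblet-like markers, and no values without them were taken. Members of the stem cell, proliferation, goblet secretion, enteroendocrine hormone and Paneth lists are also class markers, and no medians without them were taken.

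Named genes followed a rule fixed before the data were examined. In absorptive-like cells these were the 12 genes furthest apart in each direction for each pair of libraries, with at least 100 UMIs in the pair and 100 CPM in 1 of them. In stem- or cycling-like and in goblet-like cells they were the 5 furthest apart. Mitochondrial, ribosomal protein and predicted genes were left out, and list members could be named besides. Leading genes of clusters, and genes that describe a single cluster or free RNA, were chosen after their values were seen. Gene positions come from the GENCODE M21 annotation of mm10.

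The ratio and list steps were tested on simulated data drawn from the KO and WT colon absorptive-like sums, with 200 of 8789 genes changed. The draws were Poisson counts, as the intervals assume, with no variation between cells. They check the calculation only, not how well the intervals hold in real cells. Intervals of the ratio held the true ratio for 95.7% of the 8789 genes. The interval lay on the true side for 97.1% of the 68 genes changed 2-fold, and for 100% of the 68 changed 4-fold and the 64 changed 16-fold. Of 8589 unchanged genes, 0.0931% were measured at least 2-fold apart, and 6% of 100 lists of 50 unchanged genes fell outside the central 95% of random lists.

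Scaling to the median ratio of genes, in place of all UMIs, shifted every log2 ratio of WT ileum to WT colon by 0.27 in all cells and 0.22 in goblet-like cells. For KO colon to WT ileum the shift was -0.20 and -0.18. Leaving out mitochondrial genes and the 50 most abundant genes shifted the absorptive-like ratios of KO to WT colon by -0.10 and of KO to WT ileum by -0.12. The other alternatives were a stricter and a looser cell filter, doublets kept, the 5% of cells with the most UMIs removed, other clustering resolutions, all libraries clustered together, absorptive-like clusters named without region-specific markers, other minimums for list members, other thinning, the ileal share without the most abundant members, and genes matched by symbol. Alternatives chosen after seeing the data were removing the 5% of cells with the highest Scrublet scores, leaving out class markers from the lists, a stricter absorptive class and leaving out 1 KO cluster.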

Results

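Epithelial cells from the ileum and colon of adult WT mice and from the colon of Satb2 KO mice were profiled, with 1 library per group and therefore no replicate check on any difference. Satb2 encodes a chromatin-binding protein of the large-intestinal epithelium, and the comparison of KO colon with WT colon and WT ileum asked how colonic cells differ when it is deleted. Kept cells carried 49432219 UMIs in WT ileum, 48114700 in WT colon and 62274850 in KO colon. In WT ileum, WT colon and KO colon the median cell held 9607.5, 11137 and 12219.5 UMIs and 2648, 3117 and 3234 genes, in the same order. Mitochondrial genes gave a median of 7.29%, 9.75% and 10.2% of UMIs.

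Satb2 transcript was lower in KO than in WT colon and lowest in WT ileum. The gene (ENSMUSG00000038331) lies on chromosome 1 from 56793981 to 56978650 on the minus strand of mm10. It was read at 50.2 (48.2 to 52.2) UMIs per 1000000 UMIs (CPM) in WT colon, 24.6 (23.4 to 25.9) in KO colon and 6.07 (5.402 to 6.80) in WT ileum. The KO level was 2.04-fold (1.91 to 2.17) below WT colon and 4.06-fold (3.59 to 4.61) above WT ileum. Among classes, the KO level was 2.83-fold (2.49 to 3.22) below WT colon in goblet-like cells, 2.43-fold (1.77 to 3.32) in tuft-like cells, 1.86-fold (1.55 to 2.24) in absorptive-like cells, 1.66-fold (1.51 to 1.83) in stem- or cycling-like cells and 1.56-fold (1.03 to 2.37) in enteroendocrine-like cells. The labels do not state which exons were floxed, and a 3' tag outside the deleted part need not be lower, so this level does not check the deletion.

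**Figure D1:**
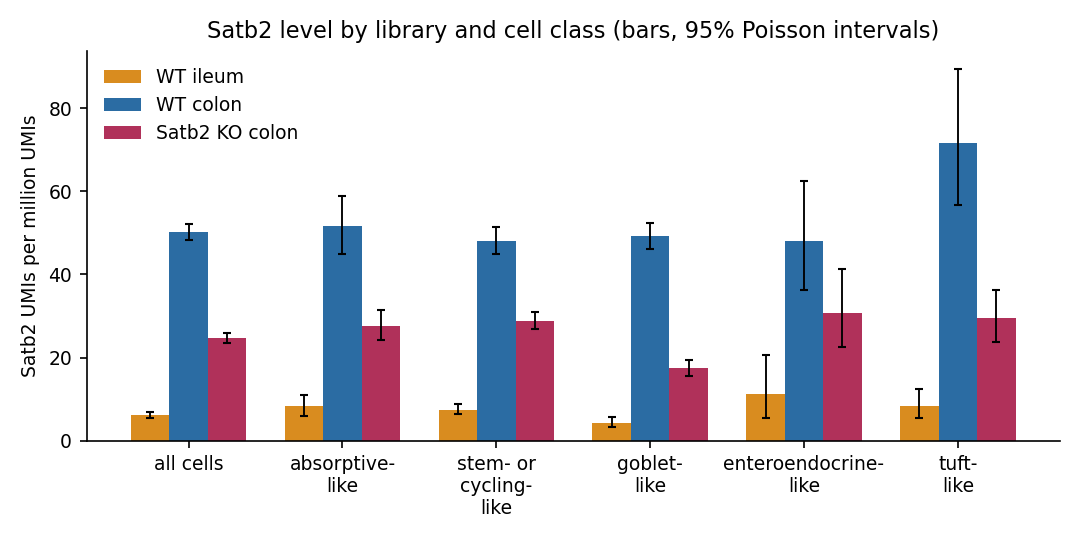
Satb2 CPM (vertical axis) in all kept cells and in 5 cell classes of the 3 libraries; bars are sums over the cells of 1 library and error bars 95% Poisson intervals. In all cells the level was 50.2 in WT colon, 24.6 in KO colon and 6.07 in WT ileum.

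The 3 libraries shared 5 epithelial classes, and a class of Paneth-like cells was found in WT ileum and KO colon. Paneth-like cells, which secrete antimicrobial defensins at the base of small-intestinal crypts, made up 9.19% (8.34 to 10.1) of WT ileum cells and 1.29% (0.987 to 1.65) of KO colon cells, and 0 of 3970 WT colon cells, with an upper limit of 0.0929%. Of the WT ileum Paneth-like cells, 118 of 394 lay in a cluster led by Retnlb, Mptx1 and Rnase1, and a KO cluster of 205 cells that shares the leading genes Retnlb, Reg4, Mmp7, Spink4 and Ptpro was named goblet-like. Defa24 stood at 106521 CPM in that ileal and 2307 CPM in that KO cluster, so the class boundary between Paneth-like and goblet-like falls differently in each library. Goblet-like cells, the mucus producers, made up 37.9% (36.3 to 39.4) of WT colon, 26.2% (25 to 27.5) of KO colon and 30.7% (29.3 to 32.1) of WT ileum. Tuft-like cells, which are chemosensory, stood at 2.59% (2.12 to 3.14) in WT colon against 5.87% (5.22 to 6.58) in KO colon and 7.0% (6.25 to 7.80) in WT ileum. Stem- or cycling-like cells held 47.3% (45.9 to 48.8) in KO colon and 41.2% (39.6 to 42.7) in WT colon, and hormone-producing enteroendocrine-like cells 3.36% (2.86 to 3.91) and 3.32% (2.79 to 3.93). Absorptive-like cells held 15.9% (14.9 to 17.0) in KO colon, 8.06% (7.23 to 8.95) in WT colon and 13.4% (12.4 to 14.47) in WT ileum. The absorptive share depended on where the class was drawn: with clusters placed at 0.5 or higher, the difference between KO and WT colon was -0.50 percentage points in place of 7.86. Other shares moved too: with the libraries clustered together, goblet-like cells held 15.9% of KO colon and 45.1% of WT ileum, and under the stricter cell filter enteroendocrine-like cells held 5.84% of KO colon.

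**Figure D2:**
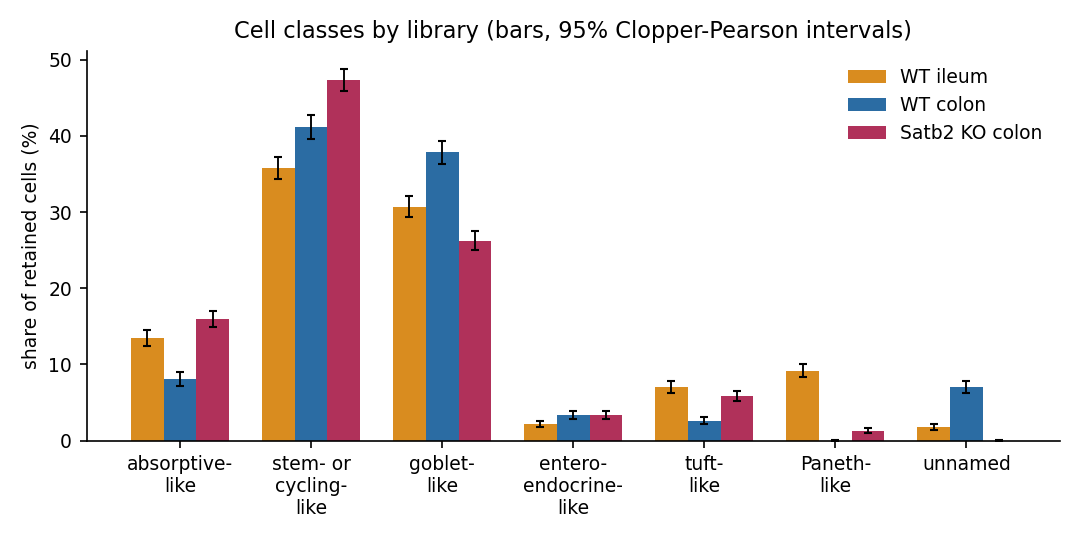
Share of kept cells (vertical axis, %) in each cell class of WT ileum, WT colon and Satb2 KO colon; bars start at 0 and error bars are 95% Clopper-Pearson intervals. Paneth-like cells stood at 9.19% in WT ileum, 1.29% in KO colon and 0 of 3970 cells in WT colon.

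The comparison of WT ileum with WT colon set the scale of the difference between the tissues. In absorptive-like cells, the bile acid carrier Fabp6 stood at 47945 (47761 to 48129.6) CPM in ileum and 4.66 (2.85 to 7.203) in colon. The apolipoprotein Apoa1, which coats absorbed lipid, stood at 7020.1 (6949.8 to 7091) and 0.233 (0.00590 to 1.30). Carbonic anhydrase 1 (Car1) stood at 37417 (37234 to 37601) in colon and 0 in ileum, at least 67793-fold lower there. Hmgcs2, the rate-limiting enzyme of ketone body synthesis, was 1218-fold (662 to 2541) lower in ileum. Over the 4 SI lists, 49 of 50 measured genes were at least 2-fold higher in ileum, with a median log2 ratio of 5.09 (4.82 to 5.30), at percentile 100 of random lists. Over both colonic lists, 16 of 23 were at least 2-fold lower in ileum and 2 higher, with a median of -2.27 (-2.70 to -1.92), at percentile 0.

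Several brush border enzymes and transporters were also far higher in ileum. Anpep, an aminopeptidase, was at least 1974-fold higher in ileum than in colon, Sis, the sucrase-isomaltase, 727-fold (311 to 2239.9) and the angiotensin-converting Ace2 823-fold (281 to 3991). The amino acid transporter Slc6a19 and the sterol transporter Npc1l1 were at least 419.7-fold and 409.7-fold higher, and the antimicrobial lectin Reg3b was 312-fold (286 to 341) higher. On the colonic side, Sult1a1, Wfdc2, Ces1d, Sycn and Prnp were 932-fold, 407-fold, 226-fold, 174-fold and 139-fold lower in ileum. Slc37a2 was at least 398-fold lower. In stem- or cycling-like cells, the stem cell gene Olfm4 was 5196-fold (2226 to 16004) higher in ileum, and Car2, Sult1a1 and Hmgcs2 were 2991-fold, 547-fold and 234-fold lower. In goblet-like cells, Hmgcs2 and Sult1a1 were read at 0.176 and 0.0881 CPM in ileum against 218 and 187 in colon. Most absorptive-like cells came from clusters led by Tmigd1, Anpep and Upp1 and by Reg3b, Mgat4c and Ms4a18 in ileum, and by Dpep1, Aqp4 and Apol10a and by Slc37a2, Mal and Ces2c in colon.

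In the main comparison, absorptive-like cells of the KO colon carried small-intestinal genes far above WT colon and most colonic genes below it. Over the 4 SI lists, 47 of 51 measured genes were at least 2-fold higher in KO than in WT colon, 0 were lower and 4 lay between. Their median log2 ratio was 3.44 (3.09 to 3.67), at percentile 100 of random lists, and 3.72 with class markers left out. Over both colonic lists, 14 of 23 were at least 2-fold lower and 4 higher, with a median of -1.84 (-2.31 to -1.77), at percentile 0, and -2.17 with class markers left out. Without regard to class, over all cells, the SI median was 3.28 (2.996 to 3.42) and the colonic median -0.97 (-1.29 to -0.94). Both medians kept their signs under every alternative run, though under the stricter cell filter no WT colon cluster was named absorptive-like and the absorptive comparison gave no value.

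Bile acid handling, a function of the ileum, was among the higher groups, with 5 of 6 measured members at least 2-fold higher and a median log2 ratio of 1.93. Fabp6 stood at 22214 (22116 to 22313) CPM in KO against 4.66 in WT colon, 4763-fold (3084 to 7798) higher. The apical bile acid transporter Slc10a2 was 4.75-fold (4.20 to 5.39) higher and the basolateral transporter subunits Slc51a and Slc51b 3.04-fold (2.84 to 3.25) and 2.53-fold (2.33 to 2.76). Fabp6 was detected in 98.9% of KO absorptive-like cells thinned to 2000 UMIs, and in 20.4% to 29.0% of the cells of each other KO class. The same share was 0.955% in WT colon and 99.8% in WT ileum absorptive-like cells, with 34, 6 and 64 shallower cells left out in KO, WT colon and WT ileum. Before thinning it was 99.3% in KO, 5.0% in WT colon and 99.8% in WT ileum.

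Lipid absorption genes were higher in 15 of 16 measured members, with a median log2 ratio of 5.51. Apoa1 stood at 1103 (1082 to 1126) CPM in KO and 0.233 in WT colon. Apoa4, another apolipoprotein, was at least 349-fold higher, the fatty acid-binding Fabp1 at least 292-fold, the retinol-binding Rbp2 123-fold (98.3 to 156) and Mttp, which loads lipid onto lipoproteins, 149.7-fold (68.6 to 408). Fabp2 went the other way, at 1281 CPM in KO and 2028 in WT colon. Brush border enzymes were higher in 13 of 15 members (median 4.62): Anpep was at least 695-fold higher, Sis 500.2-fold (214 to 1541) and Ace2 183-fold (62.6 to 890.1), while Mep1a and Alpi lay between. All 14 measured nutrient transporters were at least 2-fold higher (median 2.55), among them the amino acid transporter subunit Slc7a9 by 29.0-fold (19.9 to 44.2), the sulphate transporter Slc13a1 by 19.9-fold (15.8 to 25.4) and the glucose transporter Slc5a1 by 2.49-fold (2.21 to 2.81). Outside the lists, the galectin Lgals2 was 1932-fold (1129.8 to 3629) higher, the anion exchanger Slc26a6 at least 321-fold, and Cfhr2, at 0 UMIs in both WT libraries, at least 152-fold.

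**Figure D3:**
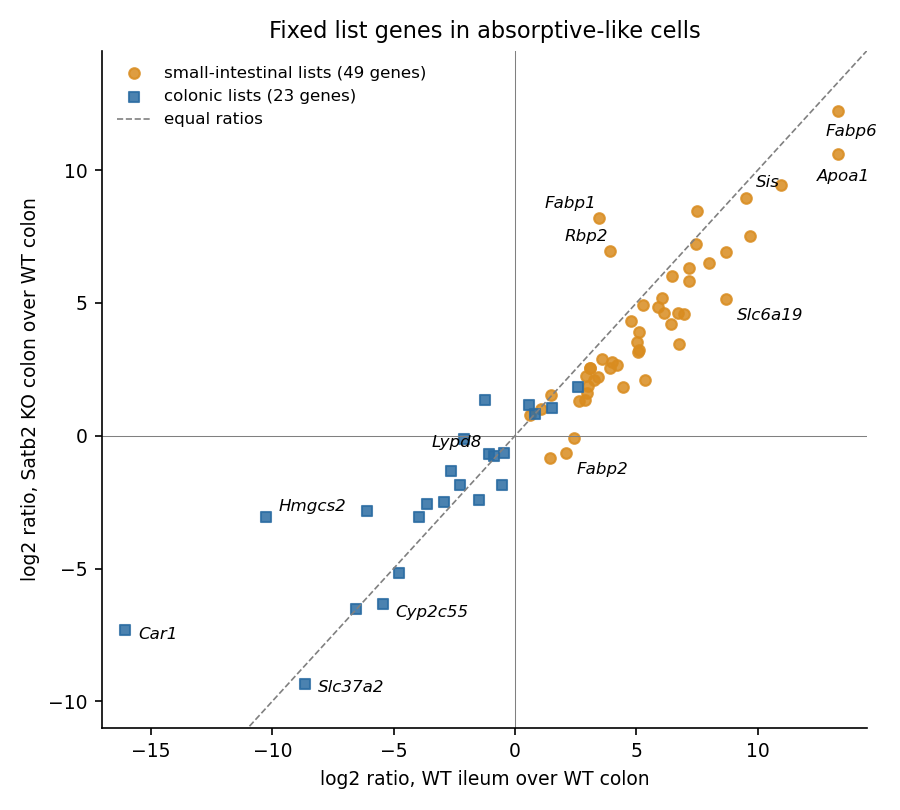
Each point is 1 gene of the fixed small-intestinal (49 genes, circles) or colonic (23 genes, squares) lists in absorptive-like cells, placed by its log2 ratio of WT ileum over WT colon (horizontal axis) and of KO colon over WT colon (vertical axis). Both axes share the WT colon library, which by itself draws points along the dashed line of equal ratios; most circles lie right of and above 0, with medians of the plotted circles of 5.08 and 3.54.

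Colonic genes were lower in KO than in WT colon with some exceptions. Of the ion and water transport list, 6 of 11 measured members were at least 2-fold lower and 2 higher, with a median log2 ratio of -1.31. Car1 stood at 232 (222 to 242) CPM in KO against 37417 in WT colon, and 3 of the 754 KO cells held 90% of its UMIs. The water channel Aqp4 was 93.1-fold (64.1 to 141) lower and the chloride-bicarbonate exchanger Slc26a3 5.405-fold (4.86 to 6.02), while Car4 and the sodium channel subunit Scnn1a were 2.22-fold (2.08 to 2.38) and 2.53-fold (1.68 to 3.95) higher. Of the other colonic list, 8 of 12 members were lower and 2 higher (median -2.55). The cytochrome P450 Cyp2c55 was 80.9-fold (73.8 to 89.0) lower, the sugar-phosphate exchanger Slc37a2 at least 645-fold and Hmgcs2 8.29-fold (7.92 to 8.67), while Lypd8, an antibacterial surface protein, lay between at 1.69-fold lower. Outside the lists, the sulphotransferase Sult1a1, the carbonic anhydrase Car2, lactoperoxidase (Lpo), Far1 and Wfdc2 were 687-fold, 516-fold, 526-fold, 183-fold and 110.2-fold lower, and St6galnac6, Prnp and Fa2h were 45.9-fold, 43.5-fold and 37.6-fold lower. The Car1 ratio rested on those few cells, and moved by up to 6.92 on the log2 scale when cells were clustered anew with doublets kept. That alternative readmitted only 2 KO cells and 1 WT colon cell, and named 750 KO cells absorptive-like in place of 754. The move therefore does not measure an effect of doublets. Of the 24 named genes, 15 moved by over 1 on that scale under some alternative, with 0 reversed. KO absorptive-like cells came from a cluster of 396 cells led by Gsdmc4, Apol10a and Mgat4c, 1 of 213 cells led by Fabp6, Slc13a1 and Slc51a, and 1 of 145 cells led by Apoa1, Apoa4 and Anpep.

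**Figure D4:**
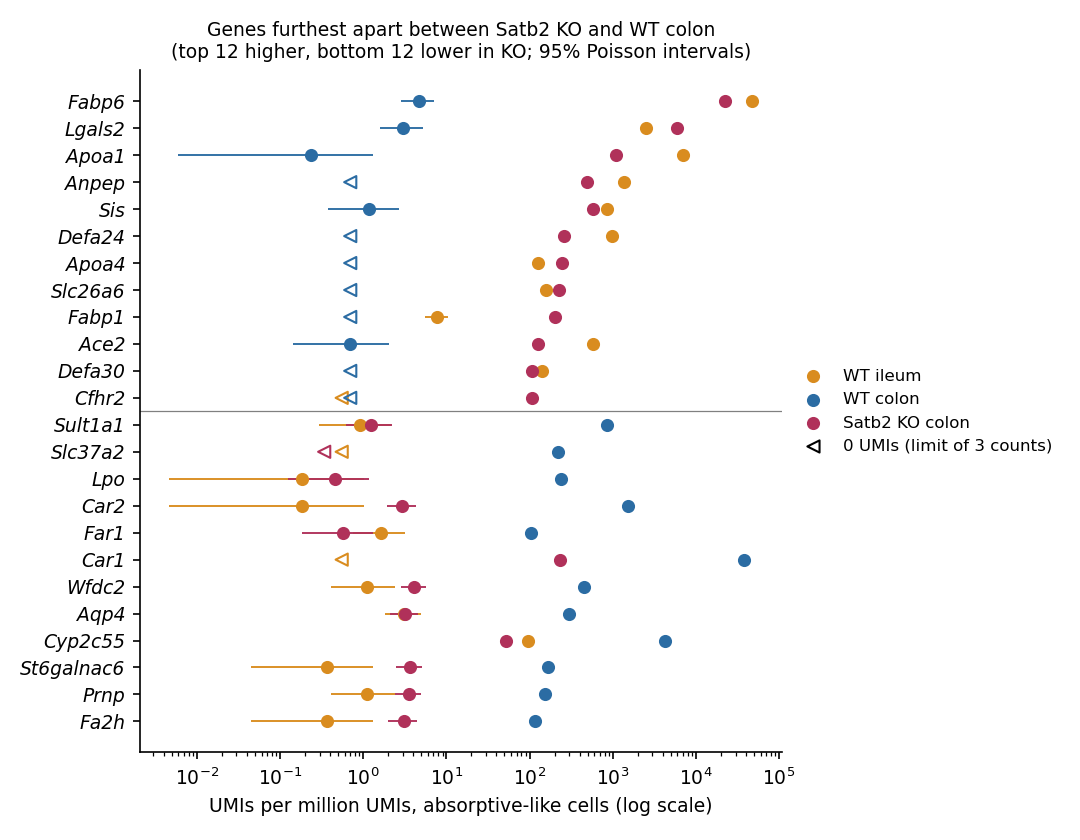
CPM in absorptive-like cells (horizontal log axis) of the 24 genes furthest apart between KO and WT colon, 12 higher and 12 lower in KO, with 95% Poisson intervals; open triangles mark 0 UMIs, drawn at the level of 3 counts. Fabp6 stood at 47945 in WT ileum, 22214 in KO colon and 4.66 in WT colon.

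In stem- or cycling-like cells the same lists differed less. The SI median log2 ratio of KO to WT colon was 1.95 (1.78 to 2.17), with 29 of 44 members at least 2-fold higher and 1 lower, and the colonic median -0.67 (-0.77 to -0.58), with 8 of 20 lower and 3 higher. Olfm4 stood at 689.9 (680.4 to 699) CPM in KO and 0.282 (0.0914 to 0.657) in WT colon, and Lgals2 was 184-fold (167 to 203) higher. Fabp6 was 97.1-fold (80.4 to 118) higher, but was detected in a similar share of thinned cells in the stem- or cycling-like (24.5%), goblet-like (21.3%), enteroendocrine-like (20.4%) and Paneth-like (23.0%) KO cells, so free RNA of absorptive-like cells was not separated from expression there, nor in the SI medians of this class and of goblet-like cells. Olfm4 was read in 39.2% of KO stem- or cycling-like cells thinned to 2000 UMIs (54.8% unthinned), against 8.55% of enteroendocrine-like and 13.1% of Paneth-like cells and 2.36% of KO absorptive-like cells (7.29% unthinned). The stem cell list as a whole had a median of -0.37 (-0.44 to -0.34), with 2 members higher, 3 lower and 8 between. Its receptor Lgr5 was 2.10-fold (1.81 to 2.44) lower and the transcription factor Sox9 2.44-fold (2.30 to 2.60) lower, while Sp5, a target of Wnt signalling, was 8.45-fold (6.33 to 11.49) higher. Of the proliferation list, 14 of 15 members lay between (median 0.24 (0.21 to 0.30)), and the replication clamp Pcna was 2.46-fold (2.17 to 2.79) higher. All of that list but Mcm2 are cycling-like markers that helped to name the class, which favours similar levels.

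Adh1, Sult1a1, Wfdc2, Car2 and Lpo were the named genes lower in KO stem- or cycling-like cells, by 57.4-fold, 50.4-fold, 46.1-fold, 38.0-fold and 30.1-fold. Most of the Car2, Sult1a1 and Lpo UMIs of the class, 571, 453 and 283, lay in 1 KO cluster of 52 cells, 1.10% (0.821 to 1.44) of KO cells, led by Sult1a1, Car1 and Car2. Car2 stood at 849.5 (781 to 922) CPM there, at 1.16 (0.798 to 1.63) in the other KO cells of the class and at 787 in WT colon. Of the 10 named genes of this class, 9 moved by over 1.5-fold under some alternative. Lpo was read at 0.0703 CPM (2 UMIs) in those other KO cells and at 294 CPM in WT colon. Defa24 and Defa30, alpha-defensins of Paneth cells, were at least 1482-fold and 636-fold higher in KO stem- or cycling-like cells and at least 374-fold and 154-fold in absorptive-like cells. These reads were not separated from free RNA of Paneth-like cells.

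Goblet-like cells of the KO colon held most secretory genes within 2-fold of the WT colon level. Of the goblet secretion list, 10 of 12 members lay between (median -0.05 (-0.06 to -0.04)). All of its genes but Atoh1 are markers that named the class, which favours similar levels in both libraries. The main intestinal mucin Muc2 was 2.61-fold (2.59 to 2.62) lower and the trefoil peptide Tff3 4.06-fold (4.02 to 4.11) higher. Muc2 ran from 6221 to 22379 CPM over the KO goblet-like clusters and from 10675 to 58144 CPM over those of WT colon. Its fold therefore does not separate class make-up from a difference in level. The lectin Zg16 stood at 7011 CPM in KO and 7040.2 in WT colon. Among named genes, the pentraxin Mptx1 was 1986-fold (1469 to 2756) lower in KO, and Meg3, Car1, Wfdc18 and Nxpe5 were 419-fold, 213-fold, 143-fold and 97.96-fold lower. Lysozyme 1 (Lyz1) was at least 5055-fold higher, Defa24 and Defa30 at least 3893-fold and 753-fold, and Lgals2 484-fold. Defa24 was detected in 43.7% of thinned KO goblet-like cells, against 45.1% of absorptive-like and 40.2% of stem- or cycling-like KO cells. By detection, free RNA of Paneth-like cells was thus not separated from defensin expression here either. The proportions differed, with 0.129 (0.122 to 0.137) Defa21 UMIs per Defa24 UMI in KO goblet-like cells against 0.282 in KO Paneth-like cells. In the other KO classes the ratio was 0.271 to 0.307. These values argue against free RNA in Paneth-like proportions as the only source in goblet-like cells of this library. Olfm4 was 497-fold higher, but its 11.1% of thinned KO goblet-like cells lay between the shares in enteroendocrine-like and Paneth-like KO cells, so free RNA was not separated from expression. Of the Lyz1 UMIs of KO goblet-like cells, 54.2% lay in the cluster of 205 cells led by Plet1, Ccl6 and Retnlb, where Lyz1 stood at 2875 CPM, against 146 to 479 CPM in the other goblet-like clusters. Defa24 stood at 2307 CPM in that cluster and at 235 to 505 CPM in the others. The SI median of KO to WT colon in goblet-like cells was 2.70 (2.46 to 3.02) and the colonic median -0.78 (-1.11 to -0.72), and with all libraries clustered together the SI median was 0.68. Of the 10 named genes, 9 moved by over 1.5-fold under some alternative, with 0 reversed.

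The Paneth cell genes of the defensin family and Lyz1 were read in the KO colon library and at 0 or 1 UMI each in WT colon, where Itln1 and Mmp7 stood at 51.1 and 10.7 CPM. All 11 list members were at least 2-fold higher in KO than in WT colon over all cells (median log2 ratio 12.76 (12.74 to 12.78), percentile 100), and all 11 were lower in KO than in WT ileum (median -2.54 (-2.55 to -2.53)), beside a smaller share of Paneth-like cells in KO. Within Paneth-like cells the log2 ratios of KO to WT ileum ran from -0.70 for Defa17 to 1.36 for Mptx2, with Defa24 at 0.23. In WT ileum against WT colon the median was 13.96. Defa24 was read at 43721 CPM in WT ileum and 7686 in KO colon, with 0 of 48114700 UMIs in WT colon. Lyz1 was read at 12449 and 1893 CPM, with 1 UMI in WT colon. Alpha-defensin genes are near-identical copies, so the division of UMIs among them is uncertain. KO Paneth-like cells were 61 in number, from 1 cluster.

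Transcription factors that set position along the gut lay mostly within 2-fold of the WT colon level in KO, and mostly within 2-fold of the WT ileum level too. Of the patterning list, 10 of 15 measured members lay between, 2 were higher and 3 lower (median -0.11 (-0.17 to -0.06)). For KO to WT ileum, 9 of 13 lay between, 3 were higher and 1 lower, so these counts do not place KO nearer to either tissue. Against WT colon, the endodermal factor Gata5 was 26.5-fold (13.8 to 58.6) higher and Gata4, on 22 KO UMIs, 3.40-fold (1.26 to 11.49) higher. The lower members were Satb2, Hoxa13 by 20.3-fold (10.8 to 43.2) and Hoxb13 by 45.3-fold (17.3 to 169). Hoxb6, Hoxb7, Hoxb8 and Hoxb9 stood at 31.7, 52.0, 50.4 and 109 CPM in KO, at 34.1, 56.0, 35.6 and 122 in WT colon and at 10.2, 27.7, 13.9 and 56.7 in WT ileum. The intestinal factor Cdx2 was 1.53-fold (1.49 to 1.57) lower in KO than in WT colon. In WT ileum against WT colon the list median was -1.01.

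The antimicrobial lectin list holds lectins of the Reg family and also Lyz2, Nos2, Duox2, Duoxa2 and Lcn2, which are not lectins. In absorptive-like cells, 7 of its 8 measured members were higher in KO than in WT colon, with 1 lower (median 4.37 (4.12 to 4.79)). Reg3b and Reg3g were 32.5-fold (29.8 to 35.5) and 33.5-fold (30.4 to 36.9) higher and Reg4 2.19-fold (1.97 to 2.44) lower. MHC class II genes, which present antigen, lay between in 5 of 7 members (median 0.64 (0.29 to 1.06)), with Cd74 and H2-Eb1 3.19-fold (2.78 to 3.66) and 3.10-fold (2.16 to 4.56) higher. WT ileum stood above WT colon in all 7 of the MHC class II genes (median 5.30) and in 7 of 8 members of the antimicrobial lectin list (median 4.90). Beside these groups, the lists of cells that the sort should exclude were also read. T lymphocyte genes had a median of -1.39 for KO to WT colon over 10 members, -0.87 for WT ileum to WT colon and -0.40 for KO to WT ileum. B and plasma cell genes had 3.40, 3.47 and -0.08 over 2 members, and myeloid genes 0.16, -1.43 and 1.59 over 4. The pan-leukocyte gene Ptprc, also read in tuft cells, stood at 4.96 CPM in KO, 2.89 in WT colon and 5.48 in WT ileum. Stroma and endothelium genes had 2.20 for KO to WT colon over 2 members, and the erythrocyte list 2.80 over 1. Dissociation stress genes had 0.08 (-0.14 to 0.14) for KO to WT colon, with 10 of 15 members between, 0.44 for WT ileum to WT colon and -0.13 for KO to WT ileum.

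Set against WT ileum, absorptive-like cells of the KO colon held small-intestinal genes at a lower level, by an extent that depended on where the class was drawn, and MHC class II genes far lower. Over the SI lists, 33 of 52 measured genes were at least 2-fold lower in KO than in WT ileum, 4 higher and 15 between (median -1.27 (-1.32 to -1.19)). With absorptive-like clusters placed at 0.5 or higher the median was -0.43, and 396 of the 754 KO cells came from a cluster placed at 0.397. The 4 list medians were -1.23 for bile acid handling, -0.60 for lipid absorption, -1.51 for brush border enzymes and -1.32 for nutrient transporters. All 7 MHC class II genes were lower (median -4.21 (-4.50 to -4.07)), H2-Aa by 60.5-fold (52.2 to 70.5) and Cd74 by 17.0-fold (16.2 to 17.9). The ubiquitin-like Ubd, the adenosine deaminase Ada, Slc6a19, the vitamin B12 receptor Cubn, Reg3b and Akr1b7 were 178-fold, 131-fold, 11.8-fold, 9.60-fold, 9.59-fold and 9.33-fold lower. The bile acid-induced hormone Fgf15 stood at 7.60 CPM in KO and 76.7 in WT ileum.

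Genes higher in KO absorptive-like cells than in WT ileum included Hmgcs2, by 147-fold (79.8 to 307), Fabp1 by 26.4-fold (19.4 to 36.8) and Rbp2 by 8.14-fold (7.71 to 8.59). The lipid absorption list that holds Fabp1 and Rbp2 had 4 members higher, 6 lower and 6 between. Bst2, Ifitm3 and Isg15, which interferon can induce, were 12.02-fold, 8.05-fold and 7.64-fold higher, and Akr1b8, Me1, Ckb and Gsta4 9.70-fold, 7.19-fold, 5.89-fold and 5.78-fold. The interferon response list as a whole had 6 members higher, 2 lower and 6 between (median -0.30). Over the colonic lists, 13 of 21 measured genes lay between, 7 were higher and 1 lower (median 0.41 (0.19 to 0.59), percentile 96.9). The medians for KO to WT ileum were 0.13 for the stem cell list, 0.15 for proliferation, -0.82 for goblet secretion, 0.34 for patterning and -0.37 for antimicrobial lectins. In WT ileum against WT colon, those lists had -0.18, 0.06 and 1.00 for stem cell, proliferation and goblet secretion. In stem- or cycling-like cells, Hmgcs2, Cda, Gsta4 and Prap1 were 35.6-fold, 4.71-fold, 4.40-fold and 4.39-fold higher in KO. In goblet-like cells, Prap1 was 25.1-fold higher, and Mptx1 and Ido1 89.4-fold and 35.0-fold lower. The goblet genes Clca1, Tpsg1, Zg16 and Ccl6 and the protease Mmp7 were 73.1-fold, 52.6-fold, 51.4-fold, 40.5-fold and 41.1-fold lower in KO stem- or cycling-like cells, and Hist1h2ap, Mki67, Birc5 and Dmbt1 53.2-fold, 16.9-fold, 15.2-fold and 17.7-fold higher in KO goblet-like cells. The directions of these 9 genes reversed when the libraries were clustered together.

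The ileal share placed KO absorptive-like cells nearer to WT ileum than to WT colon. SI list UMIs made up 91.1% (91.0 to 91.2) of all list UMIs in WT ileum absorptive-like cells, 5.34% (5.25 to 5.43) in WT colon and 79.6% (79.4 to 79.7) in KO colon. With each cell thinned to 2000 UMIs, the median cell stood at 90.4% in WT ileum (quartiles 85.8 and 95.6), 5.13% in WT colon (3.38 and 7.81) and 78.4% in KO colon (68.0 and 85.5). In stem- or cycling-like cells the share was 56.5%, 22.0% and 47.8%, and in goblet-like cells 17.4%, 5.79% and 21.0%, for WT ileum, WT colon and KO colon. The colonic lists hold Ang4 and Retnlb, which are also goblet-like markers, so the share in goblet-like cells does not measure region alone. Over all cells the ileal share was 58.8%, 7.83% and 54.8%. Its value depends on which genes are counted: without class markers the absorptive-like share was 93.7% in KO and 1.69% in WT colon, and without the 3 most abundant members of each side 78.5% and 17.5%.

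**Figure D5:**
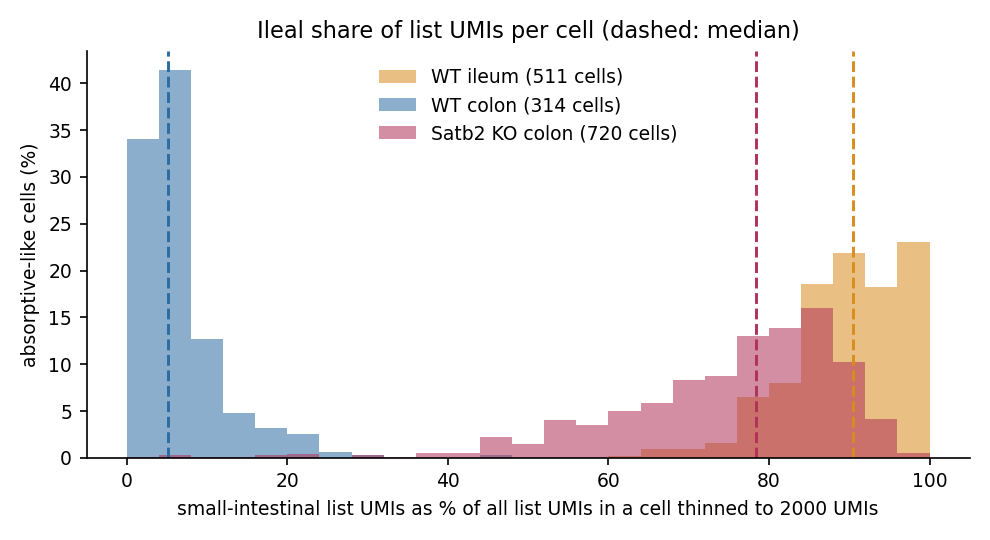
Share of small-intestinal list UMIs among all list UMIs (horizontal axis, %) per absorptive-like cell after thinning to 2000 UMIs, drawn as the percent of cells in each bin (vertical axis) for 511 WT ileum, 314 WT colon and 720 KO colon cells. Dashed lines mark medians of 90.4%, 5.13% and 78.4%.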

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

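No tests were run on the values in this part. The deposited KO matrix held counts of human (hg19) genes, which were outside every comparison. They made up 0.686% of its UMIs. A total of 13133 of its 18905 barcodes had more than 50% of their UMIs from hg19 genes, with a median of 27 UMIs each. No WT file lists hg19 genes, so no control level could be set beside these values. In kept KO cells hg19 genes made up 0.0117% of UMIs.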

How the results depend on the processing

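The alternatives with the highest Scrublet scores removed, class markers left out, absorptive-like clusters at 0.5 or higher and the colon-like KO cluster left out were tests chosen only after the results were seen, and the others were planned. No paired analysis was possible because each group held 1 library. The log2 ratio of Satb2 in KO to WT colon stayed between -1.16 and -0.95 over 13 alternatives. Satb2 and the medians over all cells are sums that do not use the classes, so alternatives that only recluster or rename cells left them unchanged. The SI and colonic medians kept their signs under each alternative that gave a value. Under the stricter filter WT colon had no absorptive-like cluster, so ratios to that class and its ileal share gave no value, and the difference in absorptive share lost its meaning. The cause of the shifts below was not tested.

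Under the stricter filter, Satb2 stood at -1.16, the KO to WT colon medians over all cells at 3.47 (SI) and -0.79 (colonic), and the KO ileal share at 80.3%. The absorptive share of KO minus WT colon came out at 5.48 percentage points there. That value is the KO share alone, set against a WT colon class that was not named, so it is no comparison. Under the looser filter, the share difference was 1.15, the medians of ileum to colon 4.71 (SI) and -1.65 (colonic), the SI median of KO to WT colon over all cells 2.84, the colonic median in absorptive-like cells -1.65, and the ileal share 80.7%. With doublets kept, the SI median of ileum to colon was 4.59 and the ileal share 80.7%. That alternative readmitted only 1 WT ileum, 1 WT colon and 2 KO cells and clustered anew. WT ileum absorptive-like cells numbered 791 there, in place of 575, so these values do not measure an effect of doublets. With the cells of most UMIs removed, the share difference was 5.79, the KO to WT colon medians in absorptive-like cells 3.68 (SI) and -1.74 (colonic), and the ileal share 80.7%. With the highest Scrublet scores removed, these were 3.68, 3.71, -1.67 and 80.6%. Resolution 0.5 gave an SI median of ileum to colon of 4.58. Resolution 2 gave a share difference of 5.73 and an ileal share of 80.7%. With the libraries clustered together, the share difference was 6.38, the SI medians 4.32 (ileum to colon) and 3.81 (KO to WT colon), the colonic median of KO to WT colon -1.47, and the ileal share 80.9%.

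Scaling by the median ratio gave a colonic median over all cells of -0.89. With no filter on members, the medians were 4.32 and -1.36 for ileum to colon, 2.83 and -1.18 for KO to WT colon in absorptive-like cells, and 2.66 and -0.92 over all cells (SI and colonic). Members with at least 100 UMIs gave an SI median of KO to WT colon of 4.22. Without the 3 most abundant members of each side the ileal share was 78.5%. With class markers left out, the SI medians of KO to WT colon were 3.72 in absorptive-like and 3.68 in all cells, the colonic medians -2.77 for ileum to colon and -1.42 for KO to WT colon over all cells, and the ileal share 93.7%. With absorptive-like clusters at 0.5 or higher, the share difference reversed to -0.50, the SI median of KO to WT colon was 4.66 and the ileal share 82.1%.

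Of the named genes of absorptive-like cells, 0 of 24 reversed in any of the 3 comparisons, over 312 values for KO to WT colon, 336 for KO to WT ileum and 288 for ileum to colon, but their folds were not stable: 24, 19 and 19 genes moved by over 1.5-fold and 15, 13 and 6 by over 1 on the log2 scale. Of the 10 named genes each of stem- or cycling-like and goblet-like cells, 9 and 9 moved by over 1.5-fold for KO to WT colon (5 and 7 by over 1 on the log2 scale, at most 6.54 and 2.80), 6 and 10 for KO to WT ileum, and 7 and 8 for ileum to colon. For KO to WT ileum, Dmbt1 in goblet-like cells reversed to a log2 ratio of -0.58 with the cells of most UMIs removed and to -1.50 with the libraries clustered together. That clustering also reversed Hist1h2ap (-1.82), Mki67 (-1.63) and Birc5 (-1.92) in goblet-like cells, and Clca1 (2.54), Tpsg1 (4.38), Zg16 (2.93), Mmp7 (1.09) and Ccl6 (3.12) in stem- or cycling-like cells. Genes under 3 UMIs in a library could be given only as levels or bounds.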

Other observations

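The test that asked whether ileal cells made up the Paneth-like cells of the KO library was written before its result was seen, and the other tests of explanations in this part were chosen only after theirs. In enteroendocrine-like cells, KO colon against WT colon had 8 of 14 measured hormone genes at least 2-fold higher and 4 lower (median log2 ratio 1.59 (1.49 to 1.70)). The gut hormones Cck, Nts and Ghrl, typical of the small intestine, were 52.3-fold (46.1 to 59.5), 507-fold (233 to 1382) and 271-fold (173 to 451) higher, and Gip at least 466-fold. Tph1, which makes serotonin, was 4.27-fold (3.93 to 4.65) lower. Insl5, typical of the colon, was counted among the lower genes on 534 UMIs from 2 WT colon cells, against 53 UMIs from 19 KO cells, so no direction is claimed for it. Few cells carried the other hormones besides: 8 KO cells held 90% of the Nts UMIs, 9 those of Gip and 11 those of Ghrl, and Nts in WT colon was 6 UMIs from 2 cells. The list stood at 1.60 in WT ileum to WT colon and -0.30 in KO colon to WT ileum. The class held 159 KO, 132 WT colon and 92 WT ileum cells. The classes differ in make-up: 73 of the WT colon cells came from a cluster led by the precursor genes Neurog3, Insm1 and Isl1, and all KO cells from 1 cluster led by Cck, Gcg and Chgb, and the comparison does not separate that from a difference in hormones. In tuft-like cells, Fabp1 was read at 2744 CPM in KO, 112 in WT colon and 948 in WT ileum.

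In absorptive-like cells, genes of cholesterol synthesis were higher in KO than in WT colon in 10 of 14 members (median 1.28 (1.13 to 1.401)), with Cyp51, Sqle and Fdps 3.40-fold, 2.90-fold and 2.76-fold higher. The same list stood at 0.91 for WT ileum to WT colon and 0.15 for KO to WT ileum. Xenobiotic metabolism genes went both ways, with 8 of 18 lower and 4 higher (median -0.72 (-0.78 to -0.64)): the glutathione transferase Gstm1 was 3.76-fold lower and the cytochrome P450 Cyp3a25 17.8-fold higher. That list stood at -0.76 for WT ileum to WT colon and 0.14 for KO to WT ileum. Interferon response genes lay between in 12 of 14 members for KO to WT colon (median 0.32 (0.28 to 0.56)), with Isg15 2.72-fold higher, and stood at 0.38 for WT ileum to WT colon and -0.30 for KO to WT ileum.

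Ileal genes were high and colonic genes low in the KO colon library. A mislabelled ileal library was argued against by Hoxb6, Hoxb7, Hoxb8 and Hoxb9, which had a median log2 ratio of 1.30 (range 0.91 to 1.86) over WT ileum and -0.11 over WT colon. A mixture of cells like those of the WT ileum and WT colon libraries was argued against by the colonic fraction it would need. In absorptive-like cells that fraction was 127.7 (98.5 to 163) percentage points higher for the same Hoxb genes than for 54 genes high in WT colon. In stem- or cycling-like cells it was 77.7 (70.3 to 86.7) higher. The Hoxb genes needed a median of 130% (range 68.2 to 176) in absorptive-like cells, above what the WT colon library itself could give. In stem- or cycling-like cells their median was 84.0% (range 64.3 to 149), which that library could give. A mixture of ileal cells with cells of another length of colon was not tested. Loss of reads to the human genes of the joint reference, as the only cause of the lowest levels, was argued against by the colon-like KO cluster. There the 12 genes lowest in KO had a median log2 ratio of 0.15 (quartiles -0.27 and 0.88) to WT colon stem- or cycling-like cells, against -6.02 in the other KO cells of the class. The cluster was picked for its high Car1, 1 of the 12 genes, which favours a high median. The WT cells were not matched to the cluster in cell type, so a smaller loss was not excluded. Colon libraries that cover different lengths of the large intestine could not be excluded, since the distal genes Hoxb13 and Hoxa13 stood at -5.50 (-7.40 to -4.11) and -4.34 in KO to WT colon and the labels name no segment. The deletion of Satb2 is the difference that the design names, and with 1 library per group it stays a hypothesis that these data could not test apart from mouse, sort and library.

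The KO colon library held Paneth-like cells and WT colon held none. Ileal cells carried into the library went with the test written before: 14 genes high in both colon libraries had a median log2 ratio of Paneth-like to other KO cells only 0.37 (-0.16 to 0.76) above that of small-intestinal list genes, which measure free RNA there. The 14 genes had few UMIs in KO Paneth-like cells, from 22 for Hmgcs2 to 0 for Car2, with counts under 3 set to 3. This result thus rests largely on counts near the floor. The median log2 ratio of KO to WT ileum Paneth-like cells, 3.38 over the 2 such genes measured, points the other way, though free RNA of the KO library could also give it, and Paneth cells need not express these genes. Doublets of other classes, which can hold no gene above its level in those classes, were argued against by the size of the Paneth gene ratios. The 11 genes stood at a median of 75.3 times (quartiles 13.3 and 85.3) their highest level in any other KO cluster. All but Habp2 also named the cluster, which favours ratios over 1 but does not set their size, and Habp2 stood at 0.947. Doublets of a Paneth cell with another cell stay open within the 61 cells. The median UMI count of these cells was 1.60 times that of the WT ileum class and 1.01 times that of its cluster with more UMIs. Carry-over from the WT ileum library would give the same Paneth gene proportions in both libraries. The log2 ratios of KO to WT ileum over the 11 genes had a median of -0.00662, which Paneth cells of another origin could also give. They ran from -0.70 for Defa17 to 1.36 for Mptx2, so the proportions were not the same for every gene. With some genes apart and others alike, the test did not decide on carry-over. Paneth-like cells formed in the KO colon and ileal cells from another source both stay open.

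A KO cluster of 52 cells, named cycling-like though led by colonic genes, held Car2 at 849.5 CPM against 787 in WT colon stem- or cycling-like cells, Car1 at 2739 against 396 and Wfdc2 at 165 against 476. Cells that escaped the deletion and WT colon cells carried into the library cannot be told apart by Satb2, which was read at 37.2 (24.1 to 54.9) CPM on 25 UMIs, against 28.7 in the other KO cells of the class and 48.0 in WT colon. The log2 ratio of the cluster to WT colon was -0.37 (-1.005 to 0.20). Too few UMIs and the unknown floxed exon keep both open, and no biological explanation was tested.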
